A study of Homo sapiens with 18 samples.

How the data were processed

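The series holds 18 Illumina bead arrays of total RNA from HEK293 cells, a human embryonic kidney line. Per the labels, endogenous p65 (RELA) was silenced with siRNA in every sample and an siRNA-resistant, HA-tagged p65 was supplied by lentivirus, either wild type (wt) or S547A. Cells of each line were untreated or given etoposide for 4 h or 8 h. This makes 6 groups of 3 arrays, and the series text describes 3 independent experiments. The dose of etoposide is not given. Per the labels' protocols, RNA was extracted with the RNeasy Mini kit, amplified with the Illumina TotalPrep-96 kit and stained with streptavidin-Cy3. The columns of the array table were joined to samples through the sample numbers in the labels.

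The deposited array table gives, per the file headers, a linear intensity of each probe on each array and a detection p-value of each probe against its own array. GenomeStudio is named in the submitters' processing notes, with no version. The intensities carry no background subtraction and no normalization between arrays, as judged from the values. A second deposited table holds linear intensities that the authors had normalized between arrays. Its columns keep the probe ranks of the same arrays (rank correlation 1, with 0.869 as the highest value between different arrays). The sorted values of its columns differ by a relative spread of at most 0.00825, which is the pattern that quantile normalization leaves. Neither table is on a log scale, and no genome build is named for either.

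The array table has 47231 probes. Gene symbols came from the probe table supplied with the series for 30112 probes with 1 symbol, while 8 probes had several symbols and 17111 had none there. Of the probes with 1 symbol, 30073 had their gene identifier in the human gene table of assembly GCF_000001405.40 GRCh38.p14, which was used for names only. Of the 495 symbols on the gene lists, 491 were resolved. Intensities were background-corrected with the detection p-values, quantile-normalized and put on the log2 scale with the neqc function of limma 3.58.1 in R 4.3.3, with an offset of 16. Probes with a detection p under 0.05 on at least 3 arrays were kept, which left 22161 probes, 16005 of them with 1 symbol. The brightest kept probe stood for each gene, and 12055 genes were tested. Of these, 3140 had more than 1 kept probe.

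Group means of all 18 arrays were fitted with limma, with 12 residual degrees of freedom, moderated variances and two-sided tests. P-values were adjusted by the Benjamini-Hochberg method over all genes within each comparison, and a gene was called at an adjusted p under 0.05. The 10 comparisons are etoposide against untreated at 4 h and at 8 h in each line, 8 h against 4 h averaged over the lines, S547A against wt in each of the 3 conditions, and the difference between the lines in the response at 4 h and at 8 h (the interaction). The camera function of limma tested 21 gene lists in each comparison, with a preset correlation of 0.01 between genes. It was run again with an estimated correlation, for which statmod 1.5.0 was loaded. The 2 runs differ also in degrees of freedom, which come from the number of genes with the preset and from the arrays (12) with the estimate. An estimate below the preset could thus still give a larger p. For apoptosis regulators in wt at 4 h the estimate was 0.00288, and the camera p 0.0197 against 0.0116. The small p-values of the preset run do not reflect the number of arrays. The lists are p53 target genes, NF-kB target genes, NF-kB pathway components, immediate early genes, DNA double-strand break repair, topoisomerases and their repair, G1/S and DNA replication, G2/M and mitosis, histone genes, apoptosis regulators, unfolded protein and integrated stress response, heat shock proteins, interferon-stimulated genes, cholesterol synthesis, ribosomal proteins, oxidative phosphorylation and housekeeping genes. The other 4 hold markers of blood, fibroblast, epithelial and keratinocyte, and neuronal cells. Groups, comparisons, gene lists, the rule for named genes and all alternatives but 3 were fixed before the data were examined. Named genes are RELA, up to 10 called genes per direction with the largest log2 change and no overlap between the arrays of the compared groups, up to 2 called members per list and direction, and TOP2A, TOP2B, TNFAIP3, CXCL8 and NFKBIA between the lines. Chance gives such an absence of overlap for 10% of genes with 3 arrays against 3.

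Where a probe was not detected on any array of the dimmer group, the change is also given as a bound, computed on each dimmer array against the lowest detected level of that array or the probe's own value, whichever was higher. Scores of a list per array, the mean over its members, were compared between lines with an exact permutation test. The fits were tested on simulated data made from these arrays, with 200 of 12055 genes changed. For wt at 8 h, the fit recovered 24% of genes changed by a log2 of 0.5, 82% at 1, 98% at 1.5 and 96% at 2, with 2.60% of calls false. For the interaction at 8 h, it recovered 8%, 54%, 82% and 88%, with 6.45% of calls false. The simulated values were independent normal draws around the overall mean of each gene, with no shared deviation of arrays or genes. The adjustment is looser where more genes change and stricter where fewer do. The real comparisons called 3583 and 3 genes, so these rates do not carry over to them.

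Alternatives were no background correction, the authors' normalized table on log2 with a pseudocount of 1, scaling to a common median in place of quantile normalization, no filter on dim probes, a stricter filter (detection p under 0.01 on all 3 arrays of a group), the mean of a gene's probes, a fit on the compared groups alone, intensity-dependent robust variances, the replicate number as a block, a minimum log2 change of 1, and each array left out in turn. The 3 settings that leave out one replicate number in every group were added after the data were seen. Between 35.8% and 39.2% of probes were detected per array. The 95th percentile of intensity was 10.8 to 16.2 times the mean background, and the number of arrays limits the precision. Probes with no symbol or several symbols were left out because their gene is not known here. A block for array slides was not fitted because the files name no slides.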

Results

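Transcript levels were measured on 18 bead arrays of HEK293 cells, a human embryonic kidney line, whose own p65 had been silenced and replaced by HA-tagged p65. RELA encodes p65, a transcription-activating subunit of NF-kB, and the replacement was either wild type (wt) or carried the S547A change. Cells of both lines were untreated or were exposed for 4 h or 8 h to etoposide, which traps topoisomerase II on DNA and leaves strand breaks. Each of the 6 groups has 3 arrays. Between 35.8% and 39.2% of probes were detected per array, median intensities ranged from 94.7 to 122, and 12055 genes were tested. Arrays of the same group correlated at r = 0.982 to 0.989 across genes, which are not independent replicates, against 0.956 to 0.988 for arrays of different groups. The comparisons ask which transcripts etoposide changes in each line and whether the S547A line responds in another way.

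RELA itself, measured by 1 probe that was detected on all arrays, was higher after etoposide in both lines. In wt cells its normalized log2 level was 7.80 ± 0.32 untreated, 9.43 ± 0.05 at 4 h and 9.22 ± 0.03 at 8 h (mean ± SD, n = 3). In S547A cells it was 8.87 ± 0.20, 10.16 ± 0.13 and 9.69 ± 0.11. RELA rose by 1.63 at 4 h and 1.43 at 8 h in wt (limma adjusted p = 1.57e-06 and 1.89e-06) and by 1.29 and 0.83 in S547A (adjusted p = 2.49e-05 and 0.000411). From 4 h to 8 h it fell by 0.33 over both lines (adjusted p = 0.0232), a call that ended without S547A replicate 3 of 4 h (adjusted p = 0.0573) or S547A replicate 2 of 8 h (0.0544). The files do not place the probe within the transcript, so endogenous and supplied RELA cannot be separated, and no cells without silencing are among the arrays.

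In wt cells at 4 h of etoposide the list of immediate early genes was higher and that of mitotic genes lower, and single cytokine and chemokine genes were among those that rose. EGR1, an immediate early transcription factor, rose from 5.51 ± 0.37 to 10.41 ± 0.26 (mean log2 level ± SD, n = 3; log2 change 4.90, adjusted p = 4e-10). The chemokine genes CCL20 and CXCL8 rose by 4.40 and 4.34, and TNFAIP3, which encodes a feedback inhibitor of NF-kB and was detected on 1 of 3 untreated arrays, by 4.11 ± 0.14 (SE; adjusted p = 1.01e-11). With its other probe CXCL8 rose by 2.35. TNF and CXCL1 were not detected in untreated wt cells and were at least 9.38-fold and 6.42-fold higher (adjusted p = 1.01e-11 and 2.18e-08). CENPA, which encodes the centromeric histone, fell by 2.20, and INHBE, which encodes an inhibin beta subunit, by 2.29 (adjusted p = 2.18e-08 and 0.000153).

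Of the 39 measured NF-kB target genes, 21 rose in wt cells at 4 h, or 25 adjusted over the list alone, with a median log2 change of 0.73 (camera adjusted p = 3.54e-25, and adjusted p = 1.54e-06 with an estimated correlation). NFKBIA, which encodes the inhibitor that holds NF-kB in the cytoplasm, rose by 2.83. Among 25 NF-kB pathway components 8 rose and 1 fell, the same numbers adjusted over the list alone (adjusted p = 0.00194, and 0.0286 with an estimated correlation). Immediate early genes rose in 14 of 22 cases, or 16 adjusted over the list alone, with DUSP1, a phosphatase gene, at 2.17 (adjusted p = 2.69e-17, and 0.00127 with an estimated correlation). Genes of G2/M and mitosis fell in 22 of 33 cases, or 28 adjusted over the list alone, with PLK1 and AURKA, which encode mitotic kinases, at -1.77 and -1.65 (adjusted p = 1.92e-25, and 0.000232 with an estimated correlation). Genes of G1/S and DNA replication rose in 7 of 26 cases, or 9 adjusted over the list alone, among them E2F2 and CDC25A, both at 0.89, and CDC25A at 0.42 with its other probe (adjusted p = 1.09e-05, and 0.00427 with an estimated correlation).

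3 further lists passed in wt cells at 4 h only in the run with the preset correlation. Apoptosis regulators rose in 5 of 21 cases, or 9 adjusted over the list alone, with MCL1, an anti-apoptotic member, at 0.89 (0.29 with its other probe) and BAK1, a pro-apoptotic one, at 0.76 (adjusted p = 0.0304, and adjusted p = 0.0689 with an estimated correlation). In the unfolded protein and integrated stress response list of 17 genes, 2 rose and 5 fell, or 2 and 8 adjusted over the list alone (adjusted p = 0.00504, and adjusted p = 0.105 with an estimated correlation). PPP1R15A, which encodes a phosphatase subunit that reverses the translation block, rose by 2.36, while DDIT4, which encodes an mTOR inhibitor, fell by 1.42. Heat shock protein genes rose in 4 of 13 cases, also 4 adjusted over the list alone, with HSPA1A at 0.70 (adjusted p = 0.0246, and adjusted p = 0.105 with an estimated correlation). In all, 1256 genes changed in wt cells at 4 h, 753 higher and 503 lower, and 120 and 72 of them by at least 2-fold.

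After 8 h in wt cells CCL20 and CXCL8 again rose, and 2 genes of the Notch pathway, DLL1 and HES5, were among those that fell. CCL20 rose by 6.18 ± 0.17 (log2 change ± SE, n = 3 per group; adjusted p = 2.66e-13), CXCL8 by 5.12 and TNFAIP3 by 4.40 (adjusted p = 6.44e-12 and 1.71e-12). The other CXCL8 probe gave 3.14. TNF, SELE, which encodes an endothelial adhesion molecule, and PI3, which encodes a protease inhibitor, were not detected in untreated wt cells and were at least 12.7-fold, 11.4-fold and 8.45-fold higher. For SELE this holds for the brighter of 2 kept probes, while the other changed by -0.54. SNHG17, a host transcript of small nucleolar RNAs, rose by 3.10 (adjusted p = 3.68e-09). BCL11A, which encodes a repressor of transcription, fell by 2.55. DLL1, which encodes a Notch ligand, fell by 2.24, HES5, a Notch target, fell by 2.31 and ID2, which encodes an inhibitor of differentiation factors, fell by 2.27 (adjusted p = 2.8e-09 for BCL11A, then 4.16e-10, 8.85e-07 and 9.35e-10).

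NF-kB target genes rose in 26 of 39 cases and 1 fell in wt cells at 8 h, or 28 and 1 adjusted over the list alone (median 1.26, adjusted p = 2.86e-17, and 1.17e-05 with an estimated correlation). BCL2L1, which encodes an inhibitor of apoptosis, was the member that fell, by 0.65, and RELB, which encodes a partner of p65, was at least 4.09-fold higher. Pathway components rose in 12 of 25 cases, also 12 adjusted over the list alone (adjusted p = 0.000149, and 0.0148 with an estimated correlation). G1/S genes rose in 18 of 26 cases, also 18 adjusted over the list alone, with E2F2 at 1.63 and CDC25A at 1.43 (adjusted p = 4.19e-07, and 0.0026 with an estimated correlation). Immediate early genes rose in 13 of 22 cases and 2 fell, or 14 and 3 adjusted over the list alone, with EGR1 at 3.07, ATF3 at 2.36 and KLF4 at -1.46 (adjusted p = 6.35e-06, and adjusted p = 0.0574 with an estimated correlation). G2/M genes split into 3 that rose and 14 that fell, the same adjusted over the list alone, with AURKB at 0.57 and PLK1 at -1.63 (adjusted p = 0.00842, and adjusted p = 0.273 with an estimated correlation).

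Stress response genes fell in 8 of 17 cases and 1 rose in wt cells at 8 h, the same adjusted over the list alone. STC2, which encodes a secreted glycoprotein, fell by 1.81 and PPP1R15A rose by 2.64 (adjusted p = 0.043, and adjusted p = 0.273 with an estimated correlation). Cholesterol synthesis genes fell in 4 of 15 cases, also 4 adjusted over the list alone, with INSIG1, a sterol-regulated gene, at -1.69 and LSS, which encodes lanosterol synthase, at -0.80 and at 0.04 with its other probe (adjusted p = 0.0371, and adjusted p = 0.0769 with an estimated correlation). In all, 3583 genes changed in wt cells at 8 h, 1994 higher and 1589 lower, and 508 and 217 of them by at least 2-fold.

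In S547A cells at 4 h the immediate early list was also higher and the mitotic list lower, and single chemokine genes were again among those that rose. TNFAIP3 was not detected in untreated S547A cells and was at least 32.2-fold higher (adjusted p = 3.94e-13). CCL20 rose by 4.76 ± 0.17, EGR1 by 4.55 ± 0.23 and CXCL8 by 4.45 ± 0.19 (log2 change ± SE, n = 3 per group). With its other probe CXCL8 rose by 3.545, against 2.352 in wt cells. SELE and PI3, also undetected before treatment, were at least 13.1-fold and 9.66-fold higher (adjusted p = 3.96e-10 and 2.32e-12), and the second SELE probe changed by 0.31. CENPA fell by 2.30 and CCNB1, which encodes the mitotic cyclin B1, by 1.78 (adjusted p = 1.02e-08 and 2.46e-08).

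In S547A cells at 4 h, NF-kB target genes rose in 24 of 39 cases, or 29 with 1 that fell adjusted over the list alone (median 1.05, adjusted p = 1.02e-31, and 3.86e-07 with an estimated correlation). Pathway components rose in 6 of 25 cases, or 8 adjusted over the list alone, among them RELB, at least 2.16-fold higher (adjusted p = 0.00134, and 0.0241 with an estimated correlation). Immediate early genes rose in 14 of 22 cases, or 16 with 1 that fell adjusted over the list alone (adjusted p = 2.09e-15, and 0.00213 with an estimated correlation). G2/M genes fell in 16 of 33 cases, or 22 adjusted over the list alone, with PLK1 at -1.59 (adjusted p = 6.5e-22, and 0.000509 with an estimated correlation). G1/S genes rose in 6 of 26 cases, or 10 adjusted over the list alone, with E2F2 at 0.89 (adjusted p = 5.78e-06, and 0.00347 with an estimated correlation). Stress response genes split into 2 that rose and 5 that fell of 17, or 2 and 9 adjusted over the list alone, with PPP1R15A at 2.58 and STC2 at -1.20 (adjusted p = 0.00344, and adjusted p = 0.112 with an estimated correlation). Heat shock genes rose in 3 of 13 cases, or 5 adjusted over the list alone (adjusted p = 0.0352, and adjusted p = 0.146 with an estimated correlation). In all, 1146 genes changed, 684 higher and 462 lower, with 128 and 64 by at least 2-fold, and the count was 711 without S547A replicate 3 of 4 h and 455 in a fit on the compared groups alone.

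At 8 h in S547A cells CCL20, SELE, TNFAIP3 and CXCL8 were among the genes that rose by the most. CCL20 rose by 6.28 ± 0.17 and CXCL8 by 5.20 ± 0.19 (log2 change ± SE, n = 3 per group; adjusted p = 6.8e-14 and 4.33e-12). The other CXCL8 probe gave 4.49, against 3.14 in wt cells, so the 2 probes differ on how alike the lines are. SELE was at least 49.8-fold higher, TNFAIP3 at least 40.2-fold, PI3 at least 22.2-fold and VCAM1, which encodes a vascular adhesion molecule, at least 7.31-fold, none of them detected before treatment. A second SELE probe changed by 0.13, and the other VCAM1 probes by 0.46 and 0.82. ZNF503, which encodes a zinc finger repressor, fell by 2.51, HOXB8, a homeobox gene, fell by 2.48, and MT1X, which encodes a metallothionein, fell by 2.19 (adjusted p = 6.38e-09, 1.3e-08 and 5.62e-08).

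NF-kB target genes rose in 31 of 39 cases and 1 fell in S547A cells at 8 h, or 33 and 1 adjusted over the list alone (median 1.68, adjusted p = 1.9e-23, and 2.15e-06 with an estimated correlation). Pathway components rose in 10 of 25 cases, also 10 adjusted over the list alone, with NFKBIA at 3.08 (adjusted p = 0.000561, and 0.0222 with an estimated correlation). G1/S genes rose in 16 of 26 cases, or 18 adjusted over the list alone, with E2F2 and CDC25A both at 1.46 (adjusted p = 2.68e-06, and 0.00442 with an estimated correlation). Immediate early genes split into 10 that rose and 4 that fell of 22, the same adjusted over the list alone, with EGR1 at 2.73 and KLF4 at -1.26 (adjusted p = 0.00358, and adjusted p = 0.19 with an estimated correlation). G2/M genes split into 3 that rose and 13 that fell of 33, or 4 and 13 adjusted over the list alone, with KIF20A, a mitotic kinesin gene, at -1.14 (adjusted p = 0.0227, and adjusted p = 0.302 with an estimated correlation). Stress response genes split into 2 that rose and 9 that fell of 17, the same adjusted over the list alone (adjusted p = 0.00613, and adjusted p = 0.156 with an estimated correlation). Cholesterol synthesis genes split into 1 that rose and 4 that fell of 15, or 1 and 5 adjusted over the list alone, with INSIG1 at -1.53 (adjusted p = 0.0335, and adjusted p = 0.0996 with an estimated correlation). In all, 3674 genes changed, 1945 higher and 1729 lower, with 499 and 237 by at least 2-fold. With arrays scaled to a common median, the median change of all genes was -0.10, with 1723 genes higher and 2294 lower.

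**Figure D1:**
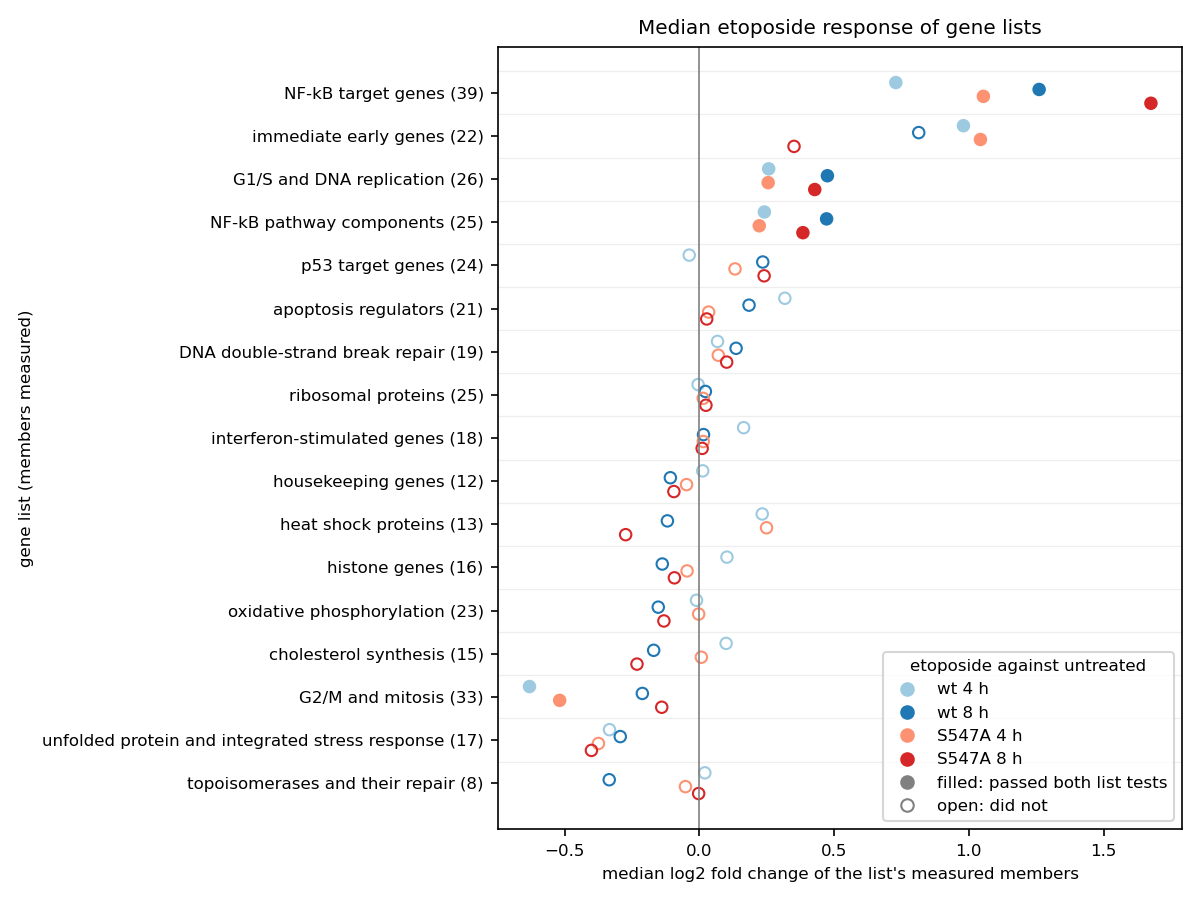
Median log2 change of the members of 17 gene lists after etoposide in wt and S547A cells at 4 h and 8 h, each against untreated cells of its line (n = 3 arrays per group); filled points passed the list test with both the preset and the estimated correlation, open points did not. The NF-kB target genes lie at 0.73 and 1.26 in wt and at 1.05 and 1.68 in S547A cells, and the G2/M genes at -0.63 and -0.21 in wt.

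Other lists fixed for the DNA damage setting did not pass in the responses of either line. Of 24 p53 target genes, 4 rose in wt and 3 in S547A cells at 4 h (5 and 3 adjusted over the list alone), and at 8 h 8 rose and 2 fell in wt and 6 rose and 3 fell in S547A cells (9 and 2, and 7 and 4, adjusted over the list alone). GADD45A, a damage-induced growth arrest gene, rose by 2.91 and 2.65 at 8 h, and CDKN1A, which encodes the cell cycle inhibitor p21, rose by 1.20 in wt, while BAX, a pro-apoptotic gene, fell by 0.65 in wt (-0.33 with its other probe) and fell by 0.92 in S547A. The list's adjusted p was 0.326 and 0.149 in wt and 0.216 and 0.178 in S547A, and in wt at 4 h its median of -0.04 and its mean of 0.11 differ in sign. Of 19 genes of DNA double-strand break repair, 3 rose in wt at 4 h, 5 rose and 4 fell in wt at 8 h, 2 rose in S547A at 4 h, and 6 rose and 2 fell in S547A at 8 h (adjusted over the list alone 4, 7 and 4, 2, and 6 and 2). EXO1, which encodes a resecting nuclease, rose in all 4 responses, by 0.94 and 1.64 in wt and by 0.86 and 1.55 in S547A. Of 8 topoisomerase genes, 2 rose and 1 fell in wt at both times (2 and 2 adjusted over the list alone), none was called in S547A at 4 h and 2 rose there at 8 h (2 and 1 adjusted over the list alone). TOP3A rose by 1.06 and TOP3B by 0.97 in wt at 8 h. TOP2A, which encodes a target of etoposide, changed by -0.49 in wt at 4 h (adjusted p = 0.043), a call that ended when any one of the 6 arrays was left out (adjusted p between 0.0533 and 0.132). Of 16 histone genes, 1 fell in wt at 4 h, 1 rose and 2 fell in wt at 8 h, 1 rose in S547A at 4 h, and 1 rose and 3 fell there at 8 h, with the same counts adjusted over the list alone.

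Of 18 interferon-stimulated genes, 2 rose in wt at 4 h, 5 rose and 2 fell in wt at 8 h, 1 rose and 1 fell in S547A at 4 h, and 4 rose and 2 fell there at 8 h, the same adjusted over the list alone. IRF7, which encodes an interferon regulatory factor, rose by 1.27 and 1.16 at 8 h, and IFITM1, an antiviral gene, fell by 0.62 in wt and fell by 0.85 in S547A. Of 23 oxidative phosphorylation genes, 1 rose and 4 fell in wt at 8 h and 1 rose and 5 fell in S547A (1 and 3, and 1 and 5, adjusted over the list alone), with SDHC, which encodes a subunit of succinate dehydrogenase, at -0.63 and -0.79, the second at -0.22 with its other probe. Of 12 housekeeping genes, 2 rose and 4 fell in wt at 8 h and 1 rose and 3 fell in S547A, the same adjusted over the list alone, with PGK1, a glycolysis gene, at -0.55 and -0.64. Of 25 ribosomal protein genes, 1 was lower in wt at 8 h, and none adjusted over the list alone. The median of this list in S547A at 8 h was 0.02, and -0.40 with arrays scaled to a common median. Markers of other cells moved in few cases. None of 7 blood markers was called over all genes, and 1 was in S547A at 4 h adjusted over the list alone. Of 10 fibroblast markers, S100A4 fell by 0.90 in S547A at 8 h. VIM, another of them, gave 0.36 there (adjusted p = 0.0382; 0.22 with its other probe) but -0.02 with arrays scaled to a common median, and its call ended without untreated S547A replicates 2 or 3 or treated replicates 1 or 2 (adjusted p between 0.0517 and 0.174). Adjusted over the list alone, 1 fibroblast marker fell in wt at 8 h and in S547A at 4 h and 8 h. Of 3 epithelial markers KRT18, a keratin gene, gave -0.82 and -0.78 in S547A (adjusted p = 0.043 and 0.0228), and -0.12 and -0.21 with its other probe. Its call ended at 4 h without untreated replicates 1 or 3 or any treated array, and at 8 h without untreated replicates 1 or 3 or treated replicate 1 (adjusted p between 0.0556 and 0.19). Adjusted over the list alone, 1 epithelial marker rose and 1 fell in S547A at 4 h and 1 fell at 8 h. Of 11 neuronal markers TUBB3, which encodes a tubulin, rose by 1.05 in wt at both times and by 1.10 and 1.06 in S547A, and NEFL, which encodes a neurofilament, fell by 1.61 in wt and by 1.81 in S547A at 8 h. Adjusted over the list alone, 1 neuronal marker was higher in wt at both times with 1 lower at 8 h, and 2 higher and 1 lower in S547A at both times.

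Between 4 h and 8 h, averaged over both lines, some transcripts rose further and others fell. SGPP2, which encodes a sphingosine phosphatase, rose by 2.50 ± 0.13, TNFRSF9, which encodes a TNF receptor family member, by 2.19 ± 0.20 and CCL20 by 1.66 ± 0.12 (log2 change ± SE, n = 6 per time; limma adjusted p = 1.26e-08, 9.88e-07 and 1.32e-07). The mitotic genes CENPA and AURKA rose by 1.77 and 1.04. GAS1, a growth arrest gene, fell by 1.86, EGR1 fell by 1.83 and ID2 fell by 1.41 (adjusted p = 1.27e-08, 1.03e-06 and 1.35e-08). In all, 1854 genes were higher at 8 h and 1524 lower, 62 and 34 of them by at least 2-fold. With arrays scaled to a common median, 1750 were higher and 1867 lower, so which direction holds more genes depends on the scaling.

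G2/M genes rose in 23 of 33 cases between the times and 1 fell, or 24 and 1 adjusted over the list alone (median 0.46, adjusted p = 3.65e-10, and 0.0129 with an estimated correlation). NF-kB target genes rose in 18 of 39 cases and 6 fell, or 20 and 6 adjusted over the list alone, with RELB at 1.28, NFKB2 at 1.20, IER3 at -1.14 and CXCL2 at -0.79 (adjusted p = 0.00275, and 0.0196 with an estimated correlation). G1/S genes rose in 14 of 26 cases and 1 fell, or 15 and 2 adjusted over the list alone, with MCM10, a replication factor gene, at 0.60 (adjusted p = 0.000807, and 0.0196 with an estimated correlation). Heat shock genes fell in 6 of 13 cases, also 6 adjusted over the list alone, with HSPA1B at -1.28 (adjusted p = 0.000481, and 0.0196 with an estimated correlation). Cholesterol synthesis genes fell in 7 of 15 cases, or 9 adjusted over the list alone, with INSIG1 at -1.21 (adjusted p = 0.000481, and 0.0129 with an estimated correlation). Pathway components split into 7 that rose and 2 that fell of 25, or 9 and 2 adjusted over the list alone (adjusted p = 0.0217, and adjusted p = 0.0974 with an estimated correlation). Immediate early genes split into 3 that rose and 10 that fell of 22, or 3 and 11 adjusted over the list alone, with KLF6 at 0.39 and KLF4 at -1.04 (adjusted p = 0.000807, and adjusted p = 0.124 with an estimated correlation). The other 14 lists did not pass between the times.

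The responses of the lines overlapped. At 4 h 453 genes rose in both lines, where independent lists would share 42.7, and 248 fell in both, against 19.3. At 8 h 1452 rose in both, against 322, and 1039 fell in both, against 228. Over all genes the log2 changes of the lines correlated at r = 0.675 (Spearman's rho 0.541) at 4 h and r = 0.822 (rho 0.738) at 8 h, described across genes, which are not independent replicates. Of the 1700 genes called in either line at 4 h, 94.9% changed with the same sign, and of 4764 at 8 h, 95.4%. The lines share no untreated arrays.

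**Figure D2:**
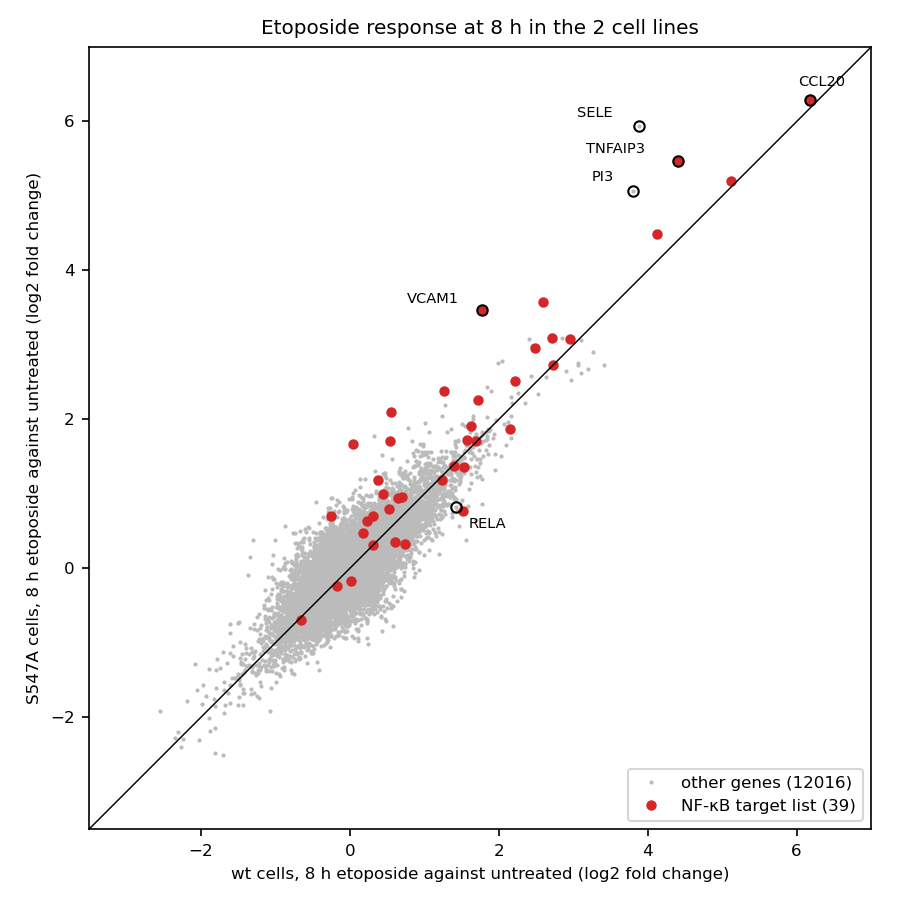
Log2 change at 8 h of etoposide against untreated in wt cells (x axis) and in S547A cells (y axis), one point per gene, with the 39 NF-kB target genes in red and all other genes in grey; the diagonal marks equal changes. SELE, PI3 and VCAM1, of which VCAM1 alone is on the list, lie above the diagonal, with differences of 2.06, 1.26 and 1.70.

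Before treatment, 5 genes differed between the lines, 3 higher and 2 lower in S547A. RELA was higher by 1.07 ± 0.15 (log2 difference ± SE, n = 3 per line, limma adjusted p = 0.018). IL32, a cytokine gene that is not on the NF-kB target list, was higher by 1.21 ± 0.19 (adjusted p = 0.0219), and by 0.34 with its other probe. TENM1, which encodes a teneurin and was not detected in S547A cells, was at least 1.65-fold lower (adjusted p = 0.0285). PDLIM5, a cytoskeletal adaptor gene, was higher by 0.98 and TET1, a DNA demethylation gene, lower by a log2 difference of -0.84, while the other probes of PDLIM5 gave 0.12 and 0.14 and those of TET1 0.17 and -0.18. The NF-kB target list had a median of 0.11 with no member called over all genes and 6 higher adjusted over the list alone (adjusted p = 0.00945, and adjusted p = 0.051 with an estimated correlation). CXCL8, NFKBIA and TNFAIP3 gave 0.79, 0.59 and 0.05 (adjusted p = 0.349, 0.392 and 0.987), and TOP2A and TOP2B 0.02 and -0.05. TNFAIP3 was not detected in untreated S547A cells, so its value is not exact. The count of 5 fell to 2, 3 and 1 without wt replicates 1, 2 and 3 and to 0, 3 and 0 without S547A replicates 1, 2 and 3, and limma called 0 genes in a fit on these 2 groups alone, where 767 genes had an unadjusted p under 0.05. RELA lost its call without S547A replicate 1 (adjusted p = 0.0588) or 3 (0.14).

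After 4 h of etoposide, 9 genes were higher and 1 lower in S547A than in wt cells, and 6 of the 9 are on the NF-kB target list, which holds neither SELE nor PI3. SELE was 3.25-fold higher (log2 difference 1.70 ± 0.19, SE, n = 3 per line; adjusted p = 0.000763), PI3 2.93-fold (adjusted p = 1.33e-05), CXCL2, which encodes a chemokine, 2.51-fold (adjusted p = 0.00545), CCL20 2.19-fold (adjusted p = 0.00754) and TNFAIP3 2.13-fold (adjusted p = 0.00329). VCAM1, not detected in treated wt cells, was at least 1.41-fold higher (adjusted p = 0.00754). The other probes gave 0.13 for SELE and 0.14 and 0.04 for VCAM1. CXCL1, TNF and HAND1, a transcription factor gene, were higher by 1.17, 0.75 and 0.66 (adjusted p = 0.0455, 0.0399 and 0.0455). CAPS, which encodes a calcium-binding protein, was the 1 gene lower, at -1.02 (adjusted p = 0.0212). CXCL8 and NFKBIA gave 0.90 and 0.68 (adjusted p = 0.161 and 0.195) and passed without background correction (adjusted p = 6.47e-05 and 0.0113). RELA gave 0.73 (adjusted p = 0.127, and 0.00237 without background correction), and TOP2A and TOP2B 0.10 and 0.02.

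Over the list, 6 of 39 NF-kB target genes were higher in S547A at 4 h, or 13 adjusted over the list alone (median 0.34, adjusted p = 6.26e-20, and 5.31e-06 with an estimated correlation). They were 6 of the 9 genes higher, against 0.0291 by chance (one-sided Fisher's exact test, p = 6.39e-14). Fisher's test takes genes as independent draws, which genes measured on the same arrays are not, so this p can overstate the evidence. Pathway components passed with a median of 0.05 and 2 members higher adjusted over the list alone, while over all genes none was called (adjusted p = 0.0197, and adjusted p = 0.141 with an estimated correlation). The count of 10 genes fell to 5, 6 and 5 without wt replicates 1, 2 and 3 and to 4 without S547A replicate 2. Without 1 array, CCL20 lost its call for wt replicate 2 (adjusted p = 0.0623), wt replicate 3 (0.0532) and S547A replicate 2 (0.0633), VCAM1 for wt replicate 1 (0.0669) and S547A replicate 2 (0.0565), CAPS for wt replicates 1 and 3 and S547A replicate 2 (0.201, 0.0652 and 0.0958), and CXCL1, TNF and HAND1 for each of the 6 arrays. A limma fit on these 2 groups alone called 0 genes, with SELE, PI3 and TNFAIP3 at adjusted p = 0.165, 0.0711 and 0.165, and with 564 genes at an unadjusted p under 0.05.

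After 8 h, 13 genes were higher in S547A than in wt cells, among them 3 of adhesion molecules, SELE, VCAM1 and ICAM1. SELE was 4.58-fold higher, at 10.91 ± 0.26 against 8.72 ± 0.03 (mean log2 level ± SD, n = 3; adjusted p = 1.61e-05), VCAM1 3.71-fold, at 8.14 ± 0.08 against 6.25 ± 0.21 (adjusted p = 1.61e-05), and PI3 2.76-fold, at 9.75 ± 0.05 against 8.28 ± 0.19 (adjusted p = 1.61e-05). CXCL2 was 2.52-fold and TNFAIP3 2.17-fold higher (adjusted p = 0.00406 and 0.00181). ICAM1, which encodes an intercellular adhesion molecule and was not detected in treated wt cells, was at least 2.18-fold higher, and BTK, which encodes a tyrosine kinase, 2.59-fold (adjusted p = 0.00544 for both). BTK was near background in these wt cells (detection p of 0.0831, 0.0974 and 0.0208), so its size is not exact. CXCL1 and CCL5 were higher by log2 differences of 1.21 and 1.03 (adjusted p = 0.0322 and 0.035), and TNFAIP2, not detected in treated wt cells, was at least 1.95-fold higher (adjusted p = 0.035). CD83, C5 and HAND1, chosen after the values were seen because they complete the 13 genes, were higher by 0.77, 0.79 and 0.66. The other SELE probe gave 0.43 and the other VCAM1 probes 0.19 and 0.69. CXCL8 and NFKBIA gave 0.86 and 0.72 (adjusted p = 0.158 and 0.144) and passed without background correction (adjusted p = 0.000102 and 0.00395). RELA gave 0.47 (adjusted p = 0.557), and TOP2A and TOP2B 0.22 and 0.13.

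The NF-kB target list passed at 8 h with 8 of 39 members higher in S547A, or 14 adjusted over the list alone (median 0.35, adjusted p = 3.04e-23, and 2.25e-06 with an estimated correlation). These were 8 of the 13 genes higher (one-sided Fisher's exact test, p = 7.09e-18), and 7 genes were higher at both times, where independent lists would share 0.0097. Both values again take genes as independent. The mean log2 level of the list's members was 7.40 ± 0.08 and 7.64 ± 0.05 in treated wt cells at 4 h and 8 h, and 7.79 ± 0.05 and 8.13 ± 0.03 in S547A (SD, n = 3), against 6.15 ± 0.03 and 6.28 ± 0.02 untreated. The treated difference of 0.44 had an exact permutation p of 0.005, the smallest that 400 arrangements can give, and 0.105 after adjustment over the 21 lists. The untreated difference of 0.13 had an exact permutation p of 0.1, the smallest that 20 arrangements can give. The other 20 lists did not pass at 8 h. The count of 13 genes fell to 5 and 8 without wt replicates 1 and 2, and to 8 and 7 without S547A replicates 1 and 3. ICAM1 lost its call without wt replicate 1 or S547A replicate 3 (adjusted p = 0.0572 and 0.0575) and BTK without wt replicate 1 (0.0562). Each of the 6 arrays, left out alone, ended the call of CXCL1, TNFAIP2 or CCL5 (adjusted p between 0.0532 and 0.191), and TNFAIP3 was at adjusted p = 0.0995 in a fit on these 2 groups alone.

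**Figure D3:**
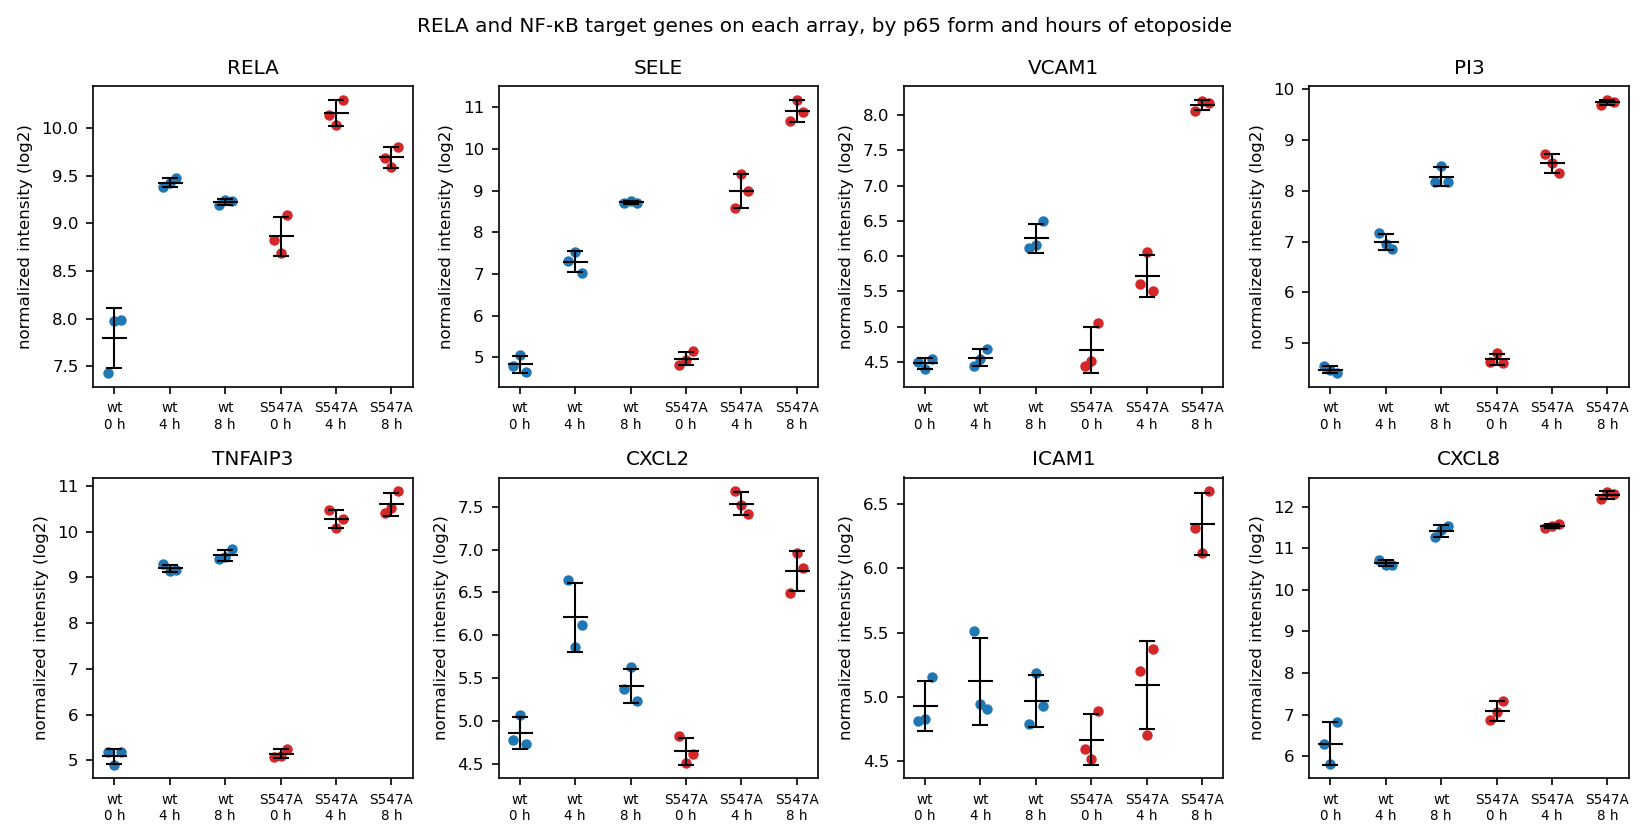
Normalized log2 level of RELA, SELE, VCAM1, PI3, TNFAIP3, CXCL2, ICAM1 and CXCL8 on each of the 18 arrays, by line and condition; points are arrays and bars the mean ± SD of 3. SELE at 8 h lies at 10.91 in S547A and 8.72 in wt cells, and RELA at 9.69 and 9.22.

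The difference between the lines in the etoposide response itself was tested as an interaction. At 8 h 3 genes passed, all with a larger increase in S547A cells: SELE by 2.06 ± 0.28, VCAM1 by 1.70 ± 0.24 and PI3 by 1.26 ± 0.18 (log2 difference of responses ± SE, n = 3 per group; adjusted p = 0.0103 for each). SELE, PI3 and VCAM1 were not detected before treatment in either line, so these differences rest on untreated levels not above background. The other SELE probe gave 0.67 and the other VCAM1 probes 0.49 and 0.48. TNFAIP3, not detected in untreated S547A cells, gave 1.06 (adjusted p = 0.103). The NF-kB target list passed, with VCAM1 as the 1 of 39 members called, or 8 larger and 1 smaller adjusted over the list alone (median 0.28, adjusted p = 1.57e-06, and 0.00161 with an estimated correlation). Immediate early genes passed in the other direction with none called over all genes and 1 smaller adjusted over the list alone (median -0.20, adjusted p = 0.0132, and adjusted p = 0.595 with an estimated correlation). Without wt replicate 1 of 8 h limma called 0 genes (adjusted p = 0.0547 for each of the 3, with 737 genes at an unadjusted p under 0.05), and PI3 lost its call also without wt replicate 3 of 8 h (0.0536) or untreated S547A replicate 3 (0.0519). With arrays scaled to a common median the differences were 1.67, 1.40 and 0.89 (adjusted p = 0.206, 0.206 and 0.38), and VCAM1 gave 0.89 as the mean of its probes (adjusted p = 0.198).

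At 4 h the response of PI3 was larger in S547A cells by 1.35 ± 0.18 (log2 difference of responses ± SE, n = 3 per group, limma adjusted p = 0.00648). That of PDLIM5 differed by -1.63 ± 0.20 (adjusted p = 0.00516) and ran in opposite directions. On wt arrays PDLIM5 read 4.975 to 5.252 untreated and 5.38 to 5.683 at 4 h (log2 level). On S547A arrays it read 5.943 to 6.295 untreated and 4.743 to 5.003 at 4 h. PI3 gave 1.03 with arrays scaled to a common median (adjusted p = 0.404) and an adjusted p of 0.0527 in a fit on the 4 groups alone. PDLIM5 was not detected in S547A cells at 4 h, and PI3 in untreated cells of either line, so neither size is exact. The other PDLIM5 probes gave 0.03 and -0.50, the mean of its probes -0.70 (adjusted p = 0.736), and the values without background correction -0.66 (adjusted p = 0.063). CXCL2, not detected in untreated cells of either line, gave 1.54 and TNFAIP3, not detected in untreated S547A cells, gave 1.04 (adjusted p = 0.0798 and 0.179). The NF-kB target list passed with none called over all genes and 7 larger adjusted over the list alone (median 0.21, adjusted p = 0.000167, and 0.00814 with an estimated correlation). RELA gave -0.34 at 4 h and -0.60 at 8 h (adjusted p = 0.946 and 0.621).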

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

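The test of the RELA difference was chosen only after the result was seen. The response to etoposide differed between the lines by the interaction test for PI3 (1.35 larger in S547A, log2) and PDLIM5 (-1.63) at 4 h, and for SELE (2.06), VCAM1 (1.70) and PI3 (1.26) at 8 h. PI3, SELE and VCAM1 were not detected in untreated cells of either line, nor PDLIM5 in S547A cells at 4 h, so these sizes are not exact. The NF-kB target list also passed, with a median of 0.21 at 4 h and 0.28 at 8 h. The immediate early list, with a median of -0.20 at 8 h, passed with the preset correlation (adjusted p = 0.0132) and not with an estimated one (adjusted p = 0.595), and none of its members was called over all genes. At 4 h, 9 of 100 splits of the 12 arrays called at least the 2 genes of the real split, with 12 as the highest count, and at 8 h 13 of 100 called at least the 3 real ones, with 13 as the highest, so chance is not excluded for either count. The highest split in both cases swaps all wt and S547A arrays within 1 condition, which turns the test into the summed difference between the lines, and the highest other split called 6 genes. PDLIM5 stood at -1.63 with its brightest probe and at 0.03 and -0.50 with its other probes, SELE at 0.67 with its other probe, and VCAM1 at 0.49 and 0.48 with its others.

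The pattern weighed here is that NF-kB target genes were higher in S547A than in wt cells after etoposide. A stronger response of the S547A line in all genes is argued against, but only for genes called in both lines. Outside the list, the median ratio of the S547A to the wt change at 8 h was 1.01 over 2467 such genes (1.00 to 1.01 over the S547A arrays). The 26 list members gave 1.11 (1.11 to 1.13). Each ratio uses the same untreated mean and the same wt change. These ranges thus hold only the spread of the treated S547A arrays, and genes called in 1 line alone are left out. The genes outside the list were not matched to its members in the size of their change. A stronger response of strongly induced genes alone is therefore not covered, and SELE and PI3, off the list, also rose more in S547A (by 2.06 and 1.26). An effect of background correction on dim probes alone is argued against too, because without it the list kept a camera p of 8.57e-30, with its median at 0.20 in place of 0.35. The amount of RELA stays open: the RELA probe read 0.47 higher in S547A at 8 h (adjusted p = 0.557, and 0.217 to 0.979 over the alternatives, so short of the threshold), and 0.73 higher at 4 h (adjusted p = 0.127, and 0.00206 to 0.609, past the threshold without background correction, in the authors' table and with intensity-dependent variances), while within groups the list mean did not follow RELA detectably (r = -0.0697, permutation p = 0.85, rho 0.028, p = 0.944, 12 arrays, 1296 arrangements, and r = -0.307 without the 2 farthest arrays). Before treatment the RELA difference was called, with mean log2 levels of 8.87 in S547A and 7.80 in wt. Its limma adjusted p was 5.32e-05 to 0.658 over the alternatives. In all conditions each S547A array read above every wt array of the same condition. The S547A change itself is what the design varies and stays open as an untested cause, since it cannot be told apart from the RELA amount or from other differences between these lines, and the pattern may reflect any of them.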

How the results depend on the processing

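The settings that leave out one replicate number in every group were chosen only after the data were seen. Called genes numbered 1256 and 3583 in wt at 4 h and 8 h, 1146 and 3674 in S547A, 3378 between the times, 5, 10 and 13 between the lines (untreated, 4 h, 8 h), and 2 and 3 in the interactions. A minimum log2 change of 1 gave 192 and 725 in wt, 192 and 736 in S547A, 96 between the times and 3 between the untreated lines. The fit on the compared groups alone gave 455 in S547A at 4 h, 0, 0 and 6 between the lines, and 1 and 5 in the interactions; it has fewer arrays, and its 0s come from limma with 767 and 564 genes at an unadjusted p under 0.05. No background correction and the authors' normalized table each gave 3 between the untreated lines, 23 between the treated lines at 8 h, and 4 in the interaction at 4 h, all 4 higher against 1 higher and 1 lower. Median scaling gave 1 and 0 in the interactions, the 1 lower (limma, with 996 genes at an unadjusted p under 0.05 at 8 h). It also gave 1723 higher and 2294 lower in S547A at 8 h, against 1945 and 1729, and 3 higher and 1 lower between the untreated lines, against 3 and 2. The strict filter gave 4 and 7 and intensity-dependent variances 4 and 5 in the interactions, and the mean of a gene's probes gave 1 between the untreated lines and 1 in the interaction at 4 h. Leaving out arrays, singly or by replicate number, gave 381 to 969 and 2063 to 3019 in wt, 328 to 1028 and 2246 to 3255 in S547A, 1880 to 3203 between the times, 0 to 3, 1 to 10 and 3 to 9 between the lines, and 0 to 3 and 0 to 4 in the interactions. The 0s come from limma with 681 to 774 genes at an unadjusted p under 0.05 between the untreated lines, 606 to 681 in the interaction at 4 h and 681 to 864 in that at 8 h. Leaving out single arrays, S547A replicate 3 of 4 h took the S547A count at 4 h to 711 and wt replicate 1 of 8 h the interaction at 8 h to 0. Each of the 6 untreated arrays took the untreated lines to 3 or fewer, the wt arrays at 4 h (5, 6 and 5) and S547A replicate 2 (4) lowered the lines at 4 h, and wt replicates 1 and 2 (5 and 8) and S547A replicates 1 and 3 (8 and 7) the lines at 8 h. Apart from fewer arrays, the cause was not tested.

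Lists that passed numbered 8 and 7 in wt, 7 and 7 in S547A, 7 between the times, 1, 2 and 1 between the lines, and 1 and 2 in the interactions. An estimated correlation gave 5 and 3 in wt, 3 in S547A at 8 h, 0 and 1 between the lines untreated (camera, 2 lists at an unadjusted p under 0.05) and at 4 h, and 1 in the interaction at 8 h. Median scaling gave 12 between the times, 2 between the untreated lines and 2 in the interaction at 4 h. The strict filter gave 2, 2 and 1 for the untreated lines and the interactions, and the mean of probes 1 between the lines at 4 h. The NF-kB target list passed in the same direction in all 10 comparisons under the 8 settings run on lists, except with the estimated correlation between the untreated lines (adjusted p = 0.051, and 1.91e-05 to 0.051 over the settings). Its medians of 0.73 and 1.26 in wt and 1.05 and 1.68 in S547A were 0.35, 0.57, 0.54 and 0.77 without background correction and 0.35, 0.56, 0.53 and 0.76 in the authors' table. The correlation between the lines was 0.675 at 4 h and 0.822 at 8 h, and 0.764 and 0.867 without background correction, 0.765 and 0.868 in the authors' table, 0.615 and 0.785 with no filter, and 0.763 and 0.865 with the strict filter.

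VIM in S547A at 8 h, 0.36, changed sign with median scaling (-0.022), which moved the median of all genes there to -0.10. Of 359 values of named genes, 52 lost their call in the fit on compared groups, 20 with median scaling, 15 with the mean of probes and 10 to 12 with no filter, no background correction, the authors' table or other variances, with 0 of 355 lost under the strict filter. With single arrays left out, 252 of 2664 values lost their call. The replicate number as a block gave 1 gene between the untreated lines and moved no other count by over 1.5 times. It ended the call of 11 named values and of 1 list, the stress response list in wt at 8 h (adjusted p = 0.052, and 0.00569 to 0.273 over the settings). As a hint from the data, 14 of 18 arrays correlated best with arrays of their own number, and same-number pairs correlated at -0.0756 to 0.213, with 14 of 45 over 0.1 against 1 of 90 other pairs. The third principal component, with 6.67% of the variance, placed replicate 1 above 2 and 2 above 3 in each of the 6 groups. In wt at 4 h, for example, their positions were 9.71, 3.06 and -8.96. Arrays of one number thus deviated together along this component, but not in every pair over all genes. The labels state no pairing, so the arrays were not treated as paired. The main fits, splits and permutations therefore ignore this shared deviation. No block for slides was run, because the files name none. Signal over background limits genes undetected in a group. Their fitted changes are not exact, and the bounds printed for some of them were computed apart from the fit. Of 118 called named values with other kept probes, 13 had a probe of opposite sign.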

Other observations

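The families and lists of this part were chosen only after the values were seen, so the tests on them, though not the splits of the arrays at the end, were chosen after the result. Genes named ZNF with a number, which mostly encode zinc finger transcription factors, rose as a group among 70 families that share the start of their symbol. In wt cells 81 of 356 rose and 4 fell at 4 h and 156 rose and 11 fell at 8 h, with median log2 changes of 0.28 and 0.40 (camera adjusted p = 0.00211 and 0.00216 with an estimated correlation). S547A cells had 86 that rose and 3 that fell at 4 h and 156 and 12 at 8 h (adjusted p = 0.00066 and 0.00169). The family's medians in wt were 0.14 and 0.21 without background correction, 0.14 and 0.20 in the authors' table, and 0.31 and 0.38 with arrays scaled to a common median. DDX genes, which encode RNA helicases, rose in 14 of 31 cases and 2 fell in wt cells at 8 h, and 15 rose and 1 fell in S547A cells (adjusted p = 0.0405 and 0.0275). DUSP genes, which encode phosphatases of MAP kinases and other targets, rose in 7 of 21 cases in wt cells at 4 h (adjusted p = 0.00734) and in 5 in S547A cells (adjusted p = 0.0694). Between 4 h and 8 h, probes named for small nucleolar RNAs read lower, with 16 of 57 SNORA genes lower and, of 71 SNORD genes, 28 lower and 1 higher. The files do not show whether these probes read the mature small RNAs or longer transcripts that contain them. In the same span 14 of 26 KIF kinesin genes rose (camera adjusted p = 0.0282 for each of these families). The SNORA and SNORD medians of -0.31 and -0.35 were -0.13 and -0.15 without background correction.

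Several host transcripts of small nucleolar RNAs were higher after etoposide. In wt cells at 8 h, SNHG17 rose by 3.10, SNHG12 by 3.06, SNHG15 by 2.53, SNHG8 by 2.07, SNHG1 by 1.94 and EPB41L4A-AS1 by 1.75, whereas DANCR and SNHG4 fell, at -0.75 and -0.77, and GAS5 gave 0.03 (adjusted p = 0.943). Of 17 measured host transcripts, 4 of them seen before the list was written, 11 rose and 2 fell there, and 10 rose and 1 fell in S547A cells. Of the other 13, 7 rose and 2 fell in wt cells, and 6 rose and 1 fell in S547A cells. A shared rise of probes of similar brightness is argued against, because the 13 hosts not seen before the list was written had a median of 0.40, above the central 95% of 10000 random lists matched on brightness (-0.25 to 0.27, highest 0.54, 17 as high). Reduced nonsense-mediated decay, a candidate explanation because many hosts are its substrates, stays open: 2 of 5 measured decay factors known to limit their own transcripts rose at 8 h in wt cells, UPF1 by 0.41 and SMG5 by 0.54, and the median of the 5 was 0.31. In S547A cells at 8 h the same 2 rose, or 4 of the 5 adjusted over the list alone, with a median of 0.42. At 4 h none of the 5 was called in either line. No biological explanation was tested beyond decay, and the design has no group that varies decay.

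Other splits of the arrays into groups of the same size were also counted. For the comparisons of 3 arrays with 3 there are 10 splits, too few for a share under 0.05. In each of them 1 of the 10, the real one, called as many genes. In wt cells the real split called 1256 genes at 4 h and 3583 at 8 h, with 0 as the highest other count by limma at both times, where the other splits had 463 to 623 and 372 to 555 genes at an unadjusted p under 0.05. In S547A cells it called 1146 and 3674, with 1 and 0 as the highest others (564 to 827 genes at an unadjusted p under 0.05 where it was 0). Between the lines it called 5, 10 and 13 genes untreated, at 4 h and at 8 h, with 1, 1 and 0 as the highest others (435 to 1014 genes at an unadjusted p under 0.05 where it was 0). For 8 h against 4 h, 1 of 100 splits, the real one, reached 3378 genes, and the highest other called 259. This is the smallest share that 100 splits can give. Other splits, here and above, mix arrays of the compared groups. Mixing raises the spread within their groups and can lower their counts.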
